A study of Rattus norvegicus with 4 samples.

How the data were processed

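Gene expression was measured in 4 libraries of rat femur mesenchymal stem cells in osteogenic induction medium, 1 per condition and all of 1 batch per the labels. Per the labels' protocols, total RNA was extracted with TRIzol, libraries were made with the QuantSeq 3' mRNA-Seq FWD kit, and single-end reads of 100 bp were taken on a NextSeq 500. The labels assign treatment by TSA and phenamil, and the design text names a different second compound, benzyl ether; this was not resolved. Per the submitters' processing notes, STAR 2.7.10b, HTSeq 2.0.2 and the build mRatBN7.2 were used, with no role or order given. The annotation, the handling of duplicates or molecular identifiers and the use of strand in counting are not given in the sources used here. Reads without molecular identifiers are not independent molecules, so all intervals and floors cover counting error only.

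The deposited table of counts holds raw whole-number counts per gene, per the file headers, for 34034 genes with Entrez identifiers and symbols. The deposited log2 values are, per the file headers, normalized data, and on checking each equalled log2 of the count divided by 1 factor per library, plus 1, within 0.000535. Those factors were 1.0002 to 1.0026 times the effective library sizes used here, on the scale of CPM. Gene identifiers were looked up in a reference table of the assembly GRCr8, a different build, in which 93.1% were found; it served only for gene spans, and no coordinates are given.

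Counts were scaled by the trimmed mean of M-values (TMM) with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test could not be run, since 1 library per group leaves no residual degrees of freedom. Genes with at least 40 counts over the 4 libraries were compared, which left 12228 genes (35.9%). Log2 ratios used a prior count of 0.5. Exact conditional binomial (Clopper-Pearson) intervals at 95% were computed for each ratio with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9. A gene was past the size rule when its whole interval lay beyond 2-fold. A count of 0 was taken to allow up to 3 counts, which is 0.271 to 0.303 CPM depending on the library.

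Before the data were examined, 42 gene lists, 26 anchor genes, the comparisons, the size rule and most alternatives were fixed. Of the lists, 35 had at least 4 members with enough counts and received a median and a percentile among 10000 random lists drawn from within 100 expression ranks of each member; 7 are described by member values. Draws past the most abundant gene were set to that gene, so percentiles of lists with very abundant members lean on it. This concerns mitochondrially encoded genes and, in part, ribosomal protein genes, among others. Counting intervals of list medians came from 200 Poisson resamplings. The named genes were to be the 8 highest and 8 lowest past the size rule with at least 100 counts, ranked by the interval bound nearest to no change, up to 2 members per list and direction, and the anchor genes. Few genes passed 2-fold with 100 counts, so after this was seen the same ranking was also applied at 1.5-fold, and up to 3 members per list and direction whose intervals excluded no change were used as examples. The genes of the plot of levels, the contrasts of library pairs and the counts of genes apart from the other libraries were likewise chosen after the data were seen. Transfer RNA and mitochondrial genes remained eligible for naming.

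The direction and overlap results set 2 differences that share the senescent control against each other. For these its counts were divided at random into 2 parts of equal expected size 100 times, beside the values without thinning and 20 simulations with no effect. All other comparisons with the senescent control, of genes and of lists, used its full counts. The size rule was tested on simulated counts with 200 changed genes among 12228: for senescent against young control it recovered 74% of genes changed 3-fold and 97% of genes changed 6-fold, called 1 unchanged gene, and its intervals covered the true ratio in 95.7% of cases. In the same test TSA against senescent control gave 72% and 97%, TSA + phenamil against senescent control 81% and 96%, and TSA + phenamil against TSA 81% and 100%. Alternatives were DESeq2 1.42.0 size factors, total counts, TMM without mitochondrial and ribosomal protein genes, no filter or a filter of 200 counts, size rules of 1.5-fold and 4-fold, the ratio alone, an assumed coefficient of variation of 0.2, thinning to the smallest total, and the deposited log2 values.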

Results

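Mesenchymal stem cells from rat femurs were cultured in osteogenic induction medium, and RNA was taken at day 1, after 24 h of treatment. Each of 4 conditions was represented by 1 library: young cells with vehicle (young control), senescent cells with vehicle (senescent control), senescent cells with trichostatin A (TSA, an inhibitor of histone deacetylases), and senescent cells with TSA plus phenamil (an amiloride derivative). No library held phenamil alone. The sample labels name phenamil as the second compound, whereas the series' design text names benzyl ether; the labels were followed here. How the cells became senescent, and the doses, are not given in the sources used here. Libraries were prepared with a 3' tag kit that reads the ends of polyadenylated transcripts. Total counts were 10905230 in the young control, 11024227 in the senescent control, 9873894 in the TSA library and 10720172 in the TSA + phenamil library. Of 34034 listed genes, 12228 with at least 40 counts over the 4 libraries were compared.

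Values below are ratios of scaled counts between 2 libraries, with 95% exact counting intervals in parentheses. These intervals cover counting error only. With 1 library per group there was no replicate spread, no p-value could be given, and every comparison describes the 2 libraries rather than the conditions. A gene was counted as past the size rule when its whole interval lay beyond 2-fold. A list member was counted as higher or lower when its interval excluded no change. Of all 12228 genes, 34.9%, 30.5%, 31.6% and 33.7% did so in the 4 main comparisons, in their order below. A simulation with no difference and an assumed coefficient of variation of 0.1 gave 3608, 3507, 3554 and 3495 such genes in that order. Observed were 4266, 3725, 3869 and 4123, so counts of members are to be read beside these. Against the young control the share was 41.2% with TSA and 31.8% with both compounds. The median log2 ratio of a list was placed among 10000 random lists matched on expression, as a description of these libraries. The libraries were close to each other: Pearson's r of log2 CPM (counts scaled to library size) across genes, which are not independent replicates, ran from 0.983 between TSA and young control to 0.989 for the closest pairs.

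The first comparison asked how senescent cells differed from young cells without treatment. Among genes with at least 100 counts, those past the size rule were higher in senescent cells for Krt7, a keratin of simple epithelia, at 2.92 (2.11 to 4.15) times the young level, the muscle enolase gene Eno3 at 2.501 (2.21 to 2.83), and the water channel gene Aqp1 at 2.45 (2.17 to 2.78). Spp1, which encodes the bone matrix protein osteopontin, went from 2337 CPM in young to 4201 CPM in senescent cells, a ratio of 1.798 (1.77 to 1.83). Tril, a co-receptor of toll-like receptor signalling, was past the rule in the other direction at 0.195 (0.119 to 0.299). Also lower were Crispld2 at 0.568 (0.527 to 0.613), the extracellular matrix gene Hmcn1 at 0.541 (0.487 to 0.601), the procollagen peptidase gene Adamts2 at 0.459 (0.349 to 0.595) and the nuclear receptor gene Nr4a1 at 0.438 (0.307 to 0.609).

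Collagen genes were lower in the senescent control: 16 of 20 were lower, 2 higher and 2 neither, with a median log2 ratio of -0.29 (-0.33 to -0.25), below all of the random lists. Col5a3 stood at 0.591 (0.561 to 0.623), Col18a1 at 0.620 (0.487 to 0.785) and Col6a1 at 0.745 (0.727 to 0.764), while Col1a1, the most abundant of them, stood at 0.980 (0.976 to 0.985). Genes of matrix assembly were split, with 11 higher, 12 lower and 10 neither of 33, and their median of -0.10 (-0.14 to 0.03) was at percentile 0.01. Among them fibrillin-1 (Fbn1) was at 0.706 (0.684 to 0.729), the procollagen enhancer Pcolce at 0.780 (0.756 to 0.804) and the crosslinking enzyme gene Lox at 1.24 (1.22 to 1.27). Genes of glycolysis and the hypoxia response were higher in 14 of 21 cases and lower in none by this rule, with a median of 0.27 (0.16 to 0.33), above all of the random lists. Lactate dehydrogenase A (Ldha) was at 1.46 (1.33 to 1.602) and phosphoglycerate mutase (Pgam1) at 1.31 (1.25 to 1.37). Cholesterol synthesis genes had 11 of 22 higher and 1 lower, a median of 0.26 (0.17 to 0.29) at percentile 99.98, with Acat2 at 1.37 (1.24 to 1.51) and Hmgcs1 at 1.27 (1.17 to 1.39). Neuronal genes had a median of 0.24 (0.09 to 0.42) at percentile 98.6, with 6 higher, 1 lower and 8 neither. Targets of TGF-beta had a median of -0.14 (-0.15 to -0.07) at percentile 0.34 but a mean of 0.005, so that median and mean differed in sign. Smad3 stood at 0.691 (0.584 to 0.816).

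Osteoblast matrix and mineral genes had 4 of 15 higher and 7 lower, with a median of -0.10 (-0.15 to 0.01) at percentile 1.71: Spp1 and the pyrophosphate-generating enzyme gene Enpp1 at 1.32 (1.27 to 1.37) were higher, and the matrix gene Sparc at 0.830 (0.824 to 0.836) was lower. This list shares Col1a1 and Col1a2 with the collagens, and Sparc, Postn, Fmod and Bmp1 with matrix assembly. Runx2, the master transcription factor of osteoblasts, was at 0.733 (0.612 to 0.876) and Bmp2 at 0.690 (0.591 to 0.804), while Bmp4 was at 1.34 (1.27 to 1.42). The osteoblast genes Sp7 and Ibsp had 0 counts in all 4 libraries, which allows up to 0.271 to 0.303 CPM. Bglap had 2, 2, 0 and 0 counts, and Dlx5 had 7, 3, 2 and 8. Of genes commonly used as senescence markers, Cdkn1a (p21) was at 0.991 (0.938 to 1.05), Lmnb1 (lamin B1) at 0.907 (0.785 to 1.05), the proliferation marker Mki67 at 0.918 (0.798 to 1.06) and Cdkn2a at 0.831 (0.572 to 1.199), all with intervals that included no change. Cdkn2b was higher at 1.297 (1.198 to 1.404). The secreted inflammatory genes Il6, Ccl2 and Mmp3 were at 1.21 (0.798 to 1.85), 0.873 (0.240 to 2.9997) and 1.13 (1.09 to 1.18). The fat cell transcription factor gene Pparg at 0.725 (0.552 to 0.946) and the BMP inhibitor gene Smad6 at 0.921 (0.807 to 1.05). The list of cycle inhibitors and senescence genes had a median of -0.05 (-0.14 to 0.07), the senescence-associated secretory list 0.01 (-0.08 to 0.14) and the mitosis list 0.02 (-0.04 to 0.09). All 3 lay within the central 95% of random lists, and the mean of the secretory list was -0.05, of the other sign than its median. In all, 14 genes were past 2-fold higher and 19 lower, and 7 of 35 lists lay outside the central 95%, where chance alone gives 1.75 if genes vary independently. The medians of the other 28 lists ran from -0.27 to 0.12. A simulation with no difference gave 0.15 genes with counting error alone, 0.45 with an assumed coefficient of variation of 0.1 between cultures and 49.2 with 0.2, against 33 observed. The standard deviation of log2 ratios in abundant genes was 0.209 and 0.414 in the last pair of simulations, against 0.178 observed; the variation of genes with few counts between cultures is not known.

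**Figure D1:**
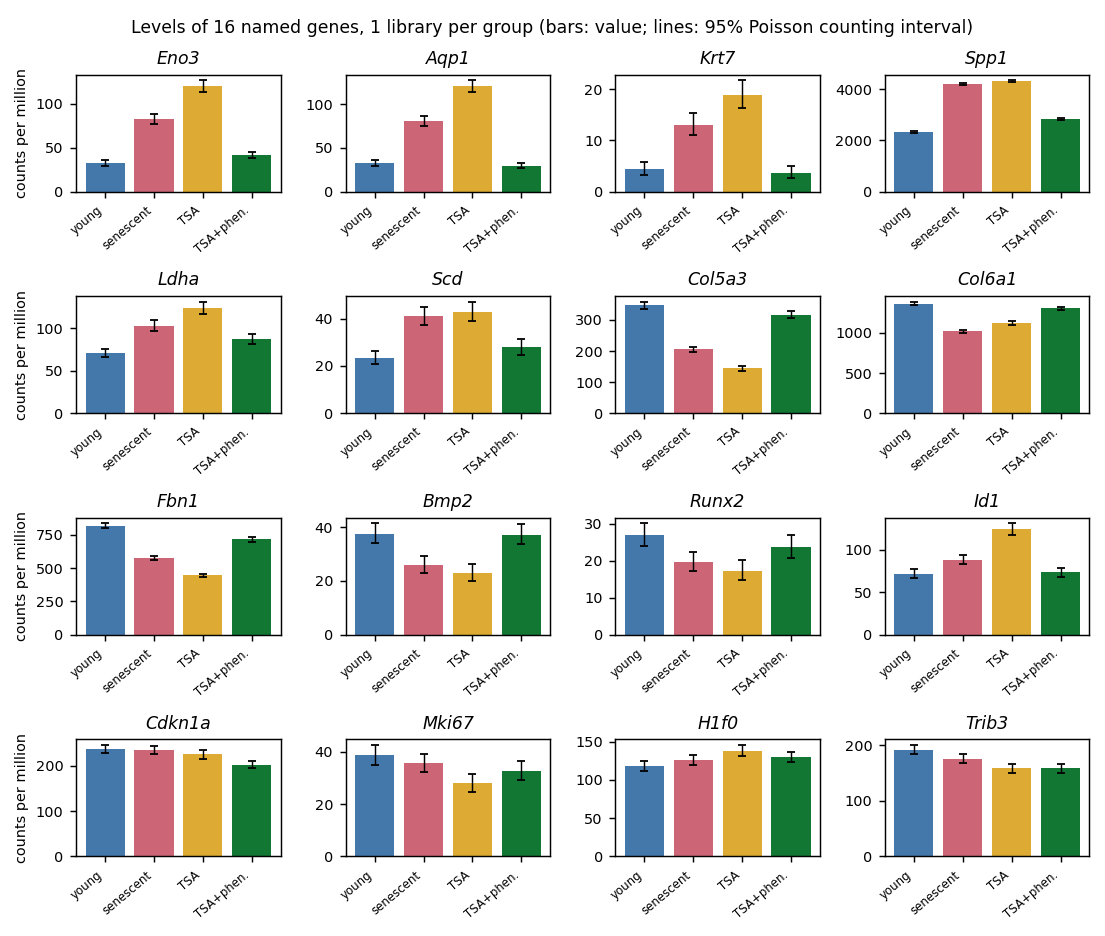
Levels of 16 genes in CPM (vertical axes, each starting at 0) in the 4 libraries, with lines for the 95% Poisson counting interval; the genes were picked for display after their values were seen. Eno3 was at 33.0, 82.5, 120.3 and 41.6 CPM in the young control, senescent control, TSA and TSA + phenamil libraries, and Col5a3 at 347, 205, 144 and 317 CPM.

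The second comparison asked how senescent cells with TSA alone differed from untreated senescent cells. Metallothionein genes were higher, with Mt1 at 1.98 (1.64 to 2.403) times and Mt2A at 1.703 (1.45 to 2.001) times the senescent control level. Also higher were the mitotic kinase gene Aurkb at 2.76 (1.91 to 4.11) and the BMP target gene Id1 at 1.405 (1.29 to 1.53). BMP targets as a list had a median of 0.01 (-0.12 to 0.08) at percentile 56.6, with 2 of 15 higher, 2 lower and 11 neither. Lower levels were found for Hpgd, which encodes the enzyme that inactivates prostaglandins, at 0.357 (0.238 to 0.517), the integrin gene Itga8 at 0.396 (0.293 to 0.524), and the receptor gene P2ry6 at 0.401 (0.268 to 0.578). The same held for the interferon-inducible RNA sensor Ifih1 at 0.441 (0.300 to 0.629) and the matrix gene Fbln2 at 0.606 (0.581 to 0.633). The muscle creatine kinase gene Ckm was at 8.22 (2.39 to 88.8), from 2 counts in the senescent control, and the microfibril gene Mfap2 at 0.215 (0.0691 to 0.488), both with few counts. Contractile genes of smooth muscle were lower in 12 of 16 cases and higher in none by this rule (median -0.17, interval -0.20 to -0.14, percentile 1.15), led by alpha smooth muscle actin (Acta2) at 0.681 (0.671 to 0.691) and Myh11 at 0.685 (0.572 to 0.816). Antioxidant genes of the NRF2 list were higher in 16 of 26 cases and lower in 1 (median 0.14, interval 0.11 to 0.19, percentile 99.95), with Nqo1 at 1.36 (1.28 to 1.44) and Hmox1 at 1.33 (1.26 to 1.41).

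Ribosomal protein genes were higher in 41 of 51 cases and lower in 1, with a median of 0.13 (0.11 to 0.16) above all of the random lists. All genes whose symbols begin like those of ribosomal proteins, a wider set than the list, took 8.91% of counts in the TSA library. In the senescent control they took 7.995%. HOX genes had a median of 0.27 (0.06 to 0.38) at percentile 99.8, with 4 higher, 2 lower and 11 neither, among them Hoxa7 at 1.45 (1.25 to 1.68) and Hoxc6 at 0.899 (0.838 to 0.963). The mitosis list had a median of -0.12 (-0.18 to -0.02) at percentile 1.69, although 4 members, Aurkb among them, were higher and 7 lower, with Plk1 at 0.737 (0.633 to 0.857) and Mki67 at 0.786 (0.671 to 0.919). Collagens had 13 of 20 lower and 3 higher, and their median of -0.14 (-0.18 to -0.12) lay just inside the central range, at percentile 2.62. Col5a3 was at 0.701 (0.655 to 0.749) and Col12a1 at 0.571 (0.495 to 0.656).

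Genes known to respond to histone deacetylase inhibitors showed little difference as a list: 5 of 17 were higher, 1 lower and 11 neither, with a median of 0.07 (0.01 to 0.12) at percentile 83.7. The linker histone gene H1f0 was at 1.095 (1.02 to 1.18), Cdkn1a at 0.961 (0.908 to 1.02) and the enzyme gene Hdac1 at 1.12 (1.03 to 1.22). Of the osteogenic genes, Runx2 was at 0.880 (0.715 to 1.08), Alpl at 0.828 (0.669 to 1.02), Bmp2 at 0.889 (0.743 to 1.06) and Spp1 at 1.03 (1.02 to 1.04). Il6 was at 0.654 (0.403 to 1.03), Mmp3 at 0.851 (0.814 to 0.889), Pparg at 1.09 (0.811 to 1.46) and Smad6 at 1.01 (0.876 to 1.16). Ccl2 was at 3.16 (1.27 to 10.3), from only 18 against 6 counts. By the size rule 7 genes were higher and 13 lower, and 5 of 35 lists lay outside the central 95%, while medians of the other 30 ran from -0.17 to 0.15. Without a count filter 34 genes were higher and 26 lower, so the balance of directions in this pair depended on the filter. The no-effect simulation gave 0.3 genes with counting error alone, 0.3 with an assumed coefficient of variation of 0.1 and 48.5 with 0.2, against 20 observed. The last pair gave standard deviations of 0.210 and 0.413 in abundant genes, against 0.168 observed.

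The third comparison set TSA plus phenamil against the senescent control. Krt7, Aqp1, Eno3 and Spp1, which were higher in senescent than in young cells, were lower with both compounds: Krt7 was at 0.281 (0.190 to 0.401) times the senescent control level, Aqp1 at 0.368 (0.322 to 0.418), Eno3 at 0.505 (0.449 to 0.566) and Spp1 at 0.674 (0.664 to 0.684). The same senescent control library enters both comparisons, for these genes and for the lists below. Error of that library alone can give opposite directions. Higher levels were found for Adamts2 at 2.51 (1.95 to 3.29), the dermal matrix gene Dpt at 2.02 (1.64 to 2.52), Notch3 at 1.94 (1.61 to 2.35), Spon1 at 1.89 (1.67 to 2.16) and Olfml2b at 1.82 (1.65 to 2.02). Collagens were higher in 12 of 20 cases and lower in 1 (median 0.18, interval 0.12 to 0.21, percentile 99.97), including Col4a2 at 1.57 (1.44 to 1.7002), Col5a3 at 1.54 (1.46 to 1.63) and Col3a1 at 1.35 (1.33 to 1.37). Glycolysis and hypoxia genes were lower in 14 of 21 cases and higher in none by this rule (median -0.24, interval -0.30 to -0.21, percentile 0.01), with Pdk1 at 0.578 (0.450 to 0.735) and Pfkl at 0.635 (0.512 to 0.782).

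Cholesterol synthesis genes were lower in 9 of 22 cases and higher in 1 (median -0.16, interval -0.22 to -0.09, percentile 0.43), with Lss at 0.622 (0.514 to 0.750) and Acat2 at 0.692 (0.623 to 0.766). Contractile genes had 9 of 16 higher and 4 lower (median 0.15, interval 0.11 to 0.16, percentile 99.7), with Actg2 at 1.78 (1.47 to 2.17) and Myh11 at 1.56 (1.36 to 1.798). Chondrogenic genes were lower in 7 of 11 cases and higher in none by this rule (median -0.25, interval -0.29 to -0.15, percentile 0.06), including Hapln1 at 0.741 (0.652 to 0.841) and Sox9 at 0.817 (0.724 to 0.922). Matrix assembly genes had 14 higher and 10 lower, with a median of 0.09 (-0.01 to 0.14) at percentile 99.7 whose counting interval included 0. Mitochondrially encoded genes were higher in 12 of 13 cases (median 0.29, interval 0.27 to 0.31), with ND4 at 1.66 (1.65 to 1.68), and their messenger RNAs took 6.85% of counts against 5.66% in the senescent control. Their median lay above all of the random lists, but for genes this abundant many draws were the single most abundant gene. Their percentiles are therefore not a guide: in senescent against young cells a median of 0.08 was at percentile 21.3. Ribosomal protein genes had a smaller median of 0.05 (0.03 to 0.07) at percentile 98.2.

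Osteoblast matrix and mineral genes had 7 of 15 higher and 5 lower, with a median of 0.17 (0.11 to 0.25) at percentile 99.9. Sparc was at 1.29 (1.28 to 1.301), Postn at 1.26 (1.18 to 1.35) and Col1a1 at 1.12 (1.12 to 1.13), whereas Enpp1 was at 0.698 (0.673 to 0.725) and Spp1, given above, was also lower. Sparc, Postn and Col1a1 also belong to the matrix assembly or collagen lists, so this median is not separate from theirs. Bmp2 was at 1.43 (1.23 to 1.68), Bmp4 at 1.27 (1.21 to 1.33), Runx2 at 1.204 (0.999 to 1.45) and Alpl at 1.12 (0.927 to 1.36). Il6 was at 0.814 (0.526 to 1.24), Ccl2 at 1.37 (0.426 to 4.89), Mmp3 at 0.953 (0.913 to 0.994), Pparg at 0.898 (0.661 to 1.22) and Smad6 at 1.15 (1.01 to 1.31). The pseudokinase gene Trib3 was at 0.901 (0.844 to 0.963), the ubiquitin ligase gene Smurf1 at 1.22 (1.03 to 1.45) and Id1 at 0.833 (0.756 to 0.916). BMP targets as a list had a median of -0.11 (-0.19 to 0.03) at percentile 6.85. By the size rule 10 genes were higher and 10 lower, and 9 of 35 lists lay outside the central 95%, while medians of the other 26 ran from -0.23 to 0.40. The no-effect simulation gave 0.1 genes with counting error alone, 0.4 with an assumed coefficient of variation of 0.1 and 46.3 with 0.2, against 20 observed. The last pair gave standard deviations of 0.209 and 0.411 in abundant genes, against 0.175 observed.

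The fourth comparison set TSA plus phenamil against TSA alone, the pair that differs by phenamil as the labels have it. At 1.2-fold, the young control, senescent control, TSA and TSA + phenamil libraries had 117, 40, 168 and 34 genes apart from the others. Differences in this pair can therefore stem from either library. Higher in the TSA + phenamil library were the lens crystallin gene Cryba4 at 4.97 (3.09 to 8.77) times the TSA level, Notch3 at 3.299 (2.62 to 4.22), Dpt at 2.98 (2.33 to 3.897), and the cartilage matrix gene Cilp at 2.88 (2.05 to 4.17). So were Smoc1 at 2.58 (2.02 to 3.34), Hmcn1 at 2.33 (2.05 to 2.67) and the leptin receptor gene Lepr at 3.91 (2.01 to 9.07). Lower were Krt7 at 0.194 (0.132 to 0.273), Aqp1 at 0.246 (0.216 to 0.279), the serotonin transporter gene Slc6a4 at 0.258 (0.180 to 0.356), and the growth factor gene Areg at 0.269 (0.159 to 0.425). Lower levels were also found for Lamb3 at 0.340 (0.249 to 0.455), Eno3 at 0.346 (0.309 to 0.386), the nucleoside transporter gene Slc29a1 at 0.430 (0.369 to 0.499) and the transfer RNA gene Trnap-agg_18 at 0.346 (0.248 to 0.471). The source of the counts at the transfer RNA gene is uncertain, since the kit reads the ends of polyadenylated transcripts. Collagens were higher in 17 of 20 cases and lower in 2, with a median of 0.33 (0.30 to 0.36) above all of the random lists. Col12a1 was at 2.31 (2.02 to 2.65) and Col5a3 at 2.2004 (2.07 to 2.34), both past the size rule.

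Contractile genes were higher in 13 of 16 cases and lower in none by this rule (median 0.24, interval 0.21 to 0.26, percentile 99.8), with Myh11 at 2.28 (1.94 to 2.696) and Acta2 at 1.65 (1.63 to 1.67). Glycolysis and hypoxia genes were lower in 15 of 21 cases (median -0.35, interval -0.37 to -0.23, below all of the random lists), with Ldha at 0.704 (0.645 to 0.767) and Pkm at 0.719 (0.683 to 0.756), and Vegfa was the exception at 1.22 (1.05 to 1.41). Cholesterol synthesis genes were lower in 10 of 22 cases (median -0.16, interval -0.21 to -0.06, percentile 0.66), including Insig1 at 0.727 (0.650 to 0.813). Antioxidant genes were lower in 13 and higher in 4 of 26 cases (median -0.13, interval -0.17 to -0.07, percentile 0.51), with Nqo1 at 0.685 (0.644 to 0.727). Ribosomal protein genes were lower in 34 of 51 cases (median -0.08, interval -0.10 to -0.07, percentile 1.01). Genes known to respond to histone deacetylase inhibitors were lower in 8 of 17 cases and higher in none by this rule, with a median of -0.15 (-0.21 to -0.08) just inside the central range at percentile 2.66. Interferon genes had a median of 0.27 (0.14 to 0.45) at percentile 97.9, but 12 of 15 were neither higher nor lower, and Ifih1 stood at 1.86 (1.28 to 2.76).

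Of the osteogenic genes, Runx2 was at 1.37 (1.12 to 1.67), Alpl at 1.36 (1.103 to 1.67), Bmp2 at 1.61 (1.37 to 1.91), Col1a1 at 1.26 (1.25 to 1.26) and Spp1 at 0.655 (0.645 to 0.665). As lists, osteogenic transcription factors had a median of 0.04 at percentile 62.6, with 2 of 6 higher and 4 neither. Osteoblast matrix and mineral genes had a median of 0.23 at percentile 96.9, with 8 of 15 higher and 4 lower. Both lay inside the central range. Il6 was at 1.24 (0.765 to 2.06), Ccl2 at 0.434 (0.158 to 1.01), Mmp3 at 1.12 (1.07 to 1.17), Pparg at 0.826 (0.607 to 1.12) and Smad6 at 1.14 (0.996 to 1.31). Id1 was at 0.593 (0.541 to 0.649), Smurf1 at 1.32 (1.104 to 1.59) and for Trib3 the interval of 0.933 to 1.07 included no change. The BMP target list had a median of -0.07 (-0.22 to 0.003) at percentile 19.6, with 3 higher and 6 lower of 15. By the size rule 30 genes were higher and 20 lower, and 7 of 35 lists lay outside the central 95%, while medians of the other 28 ran from -0.41 to 0.27. Scaling by total counts alone gave 20 higher and 23 lower, so the balance of higher against lower genes in this pair depended on the scaling. The no-effect simulation gave 0.2 genes with counting error alone, 0.6 with an assumed coefficient of variation of 0.1 and 46.4 with 0.2, against 50 observed. The last pair gave standard deviations of 0.211 and 0.415 in abundant genes, against 0.219 observed.

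**Figure D2:**
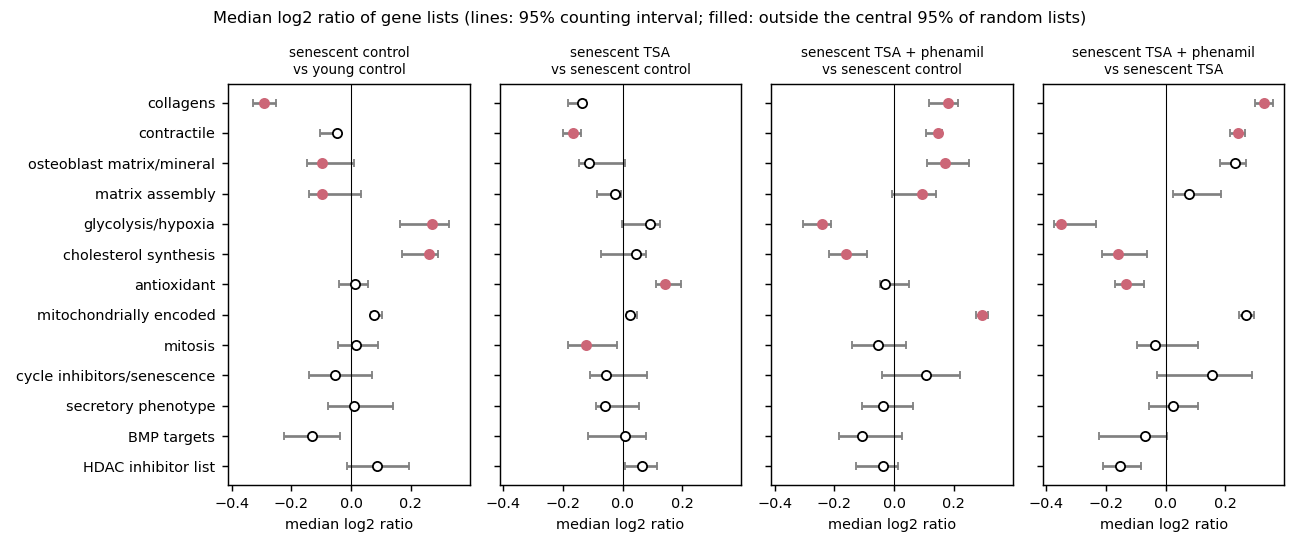
Median log2 ratio (horizontal axis) of 13 gene lists in the 4 main comparisons, with lines for the 95% counting interval; filled points lie outside the central 95% of random lists matched on expression. Collagens were at -0.29 in senescent against young cells and 0.33 in TSA + phenamil against TSA, and glycolysis and hypoxia genes at 0.27 and -0.35. For mitochondrially encoded genes the random draws lean on the most abundant gene, so the filling of those points is not a guide.

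Each treated library was also set against the young control. With TSA alone, Aqp1 was at 3.65 (3.25 to 4.12) times the young level, Eno3 at 3.65 (3.24 to 4.11), Spp1 at 1.85 (1.82 to 1.88), Bmp2 at 0.614 (0.519 to 0.722) and Runx2 at 0.645 (0.530 to 0.780). With TSA plus phenamil the same genes were at 0.900 (0.771 to 1.05), 1.26 (1.095 to 1.45), 1.21 (1.19 to 1.23), 0.990 (0.860 to 1.14) and 0.882 (0.742 to 1.05). Collagens had 18 of 20 lower than in young cells and 1 higher with TSA (median -0.39, interval -0.42 to -0.37, below all of the random lists). With both compounds 11 were lower, 5 higher and 4 neither (median -0.05, interval -0.08 to -0.04, percentile 1.17). Glycolysis and hypoxia genes had medians of 0.31 (0.23 to 0.40) with TSA and 0.03 (-0.08 to 0.09) with both, at percentiles 100 and 64.4. Genes known to respond to histone deacetylase inhibitors had a median of 0.23 (0.18 to 0.31) at percentile 98.7 with TSA, 11 of 17 higher, and 0.08 (0.00 to 0.13) at percentile 83.8 with both. Mitochondrially encoded genes had a median of 0.37 (0.36 to 0.39) with both compounds, above all of the random lists, and 0.15 (0.11 to 0.18) with TSA at percentile 96.7. For this list the random draws lean on the most abundant gene, so these percentiles are not a guide. Past the size rule were 44 genes higher and 43 lower with TSA, and 16 higher and 12 lower with TSA plus phenamil, beside the 14 and 19 of the untreated senescent control. The no-effect simulation gave 0.6 and 0.4 genes with an assumed coefficient of variation of 0.1 and 44.1 and 48.2 with 0.2, against 87 and 28 observed. In abundant genes the observed standard deviations were 0.275 and 0.178, and the difference between the 2 distances was not tested.

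The design also allows the question of whether treated senescent cells differed from untreated ones in the direction of the young level. The senescent control enters both differences, so its counts were divided at random into 2 parts of equal expected size, 100 times, with a separate part for each difference. Of the 21 genes (on average 21.3) that were past 2-fold between senescent and young cells, 80.2% differed in the direction of the young level with TSA plus phenamil (17 of 21, 95% exact binomial interval 58.1% to 94.6%), against 49.1% in a simulation with no treatment effect. With TSA alone the share was 48.6% (10 of 21, 25.7% to 70.2%), against 51.3% simulated. Without the split the shares were 97.0% and 75.8%, against 72.5% and 78.2% simulated, which shows how far a shared control alone moves them. The split removes shared counting error but not any other error of the 1 senescent control library. Such an error can raise the share, and the simulation held counting error only. The binomial intervals rest on rounded means over the splits and treat genes as independent, which they are not.

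Differences from the senescent control were then compared between the 2 treatments. With the control split, the log2 ratios correlated across 12228 genes at r = 0.231, against -0.00298 simulated with no effect. Without the split r was 0.443, against 0.479 simulated, and the covariance exceeded the simulated one by 0.0516 with the split and 0.0534 without it. Few genes were past 2-fold in both: 0.46 on average with the split, all lower, where lists independent of each other would share 0.00817, and 1 without it. Any other error of the shared control library enters both ratios and adds to the correlation and to the covariance difference.

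**Figure D3:**
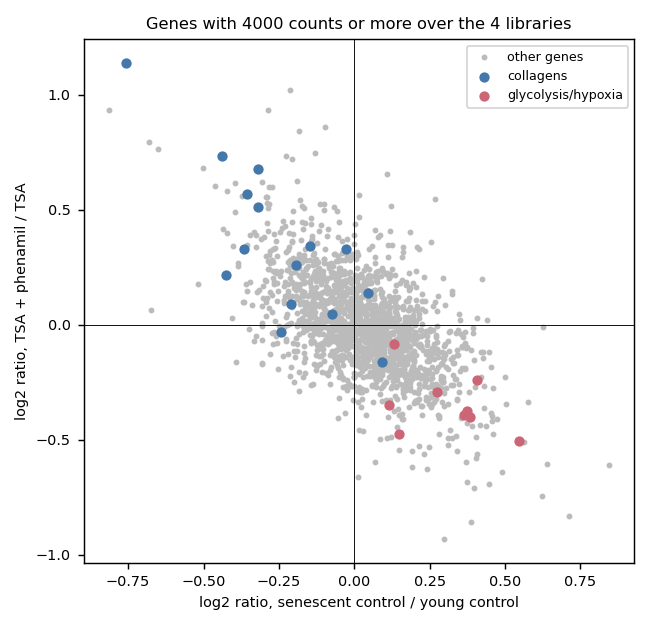
Log2 ratio of senescent over young control (horizontal axis) against log2 ratio of TSA + phenamil over TSA (vertical axis), 2 ratios with no library in common, for 1769 genes with at least 4000 counts over the 4 libraries; each point is a gene, with collagens and glycolysis and hypoxia genes coloured. Across these genes senescent over young correlated with TSA over TSA + phenamil, the inverse of the vertical axis, at r = 0.594 (0.557 to 0.631 over 1000 resamplings of genes). Genes are not independent replicates. This pairing follows the contrast with the greatest variance, picked after the data were seen, so its r is above 0 by algebra. The other pairings without a common library gave -0.445 and 0.2045 over the same genes. Their signs also follow by algebra from the variances of the contrasts, so they are no separate evidence.

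Markers of cells that a marrow-derived culture could also hold were scarce. Myeloid markers summed to 6.14, 7.36, 13.4 and 13.1 CPM in the young control, senescent control, TSA and TSA + phenamil libraries, erythroid markers to 1.99, 1.91, 3.74 and 3.15 CPM, and lymphoid markers to 2.08, 2.0, 1.31 and 2.10 CPM. Endothelial markers summed to 34.9, 25.4, 27.3 and 26.4 CPM, most of it Egfl7, which was at 0.640 (0.532 to 0.766) in senescent against young cells. Osteoclast markers summed to 74.6, 84.5, 77.6 and 67.0 CPM, most of it the protease gene Ctsk with 514, 560, 457 and 442 counts, which mesenchymal cells can also express. Of the channels and exchangers that amiloride-type compounds block, the sodium-calcium exchanger Slc8a1 had 315, 234, 212 and 239 counts, and the sodium channel gene Scnn1a had 9, 2, 7 and 3. The Y-linked genes Kdm5d, Eif2s3y and Uty were detected in all 4 libraries. Metallothionein, histocompatibility, ribosomal protein and mitochondrially encoded genes share sequence with close copies or overlap each other, and their single values are uncertain for that reason.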

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

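All alternatives were planned ahead except the 1.5-fold rule for the direction and overlap results. In the 4 main comparisons, no list median outside the central range and no named gene whose interval excluded no change took the other sign under the scalings, the thinning, the deposited values or, for lists, the filter of 200 counts. Some values close to 0 did. Values are given in the order senescent against young control, TSA against senescent control, TSA + phenamil against senescent control, TSA + phenamil against TSA, TSA against young and TSA + phenamil against young, where the size rule gave 33, 20, 20, 50, 87 and 28 genes. Without a count filter there were 106, 60, 77, 94, 167 and 116 genes, and with at least 200 counts 5, 1, 2, 17, 27 and 1. A 1.5-fold rule gave 165, 131, 133, 223, 387 and 128 genes and a 4-fold rule 2, 0, 0, 2, 3 and 2. The ratio alone, without its interval, gave 557, 500, 497, 553, 712 and 470 genes, and the deposited log2 values, which carry no interval, 135, 128, 103, 169, 286 and 110. An assumed coefficient of variation of 0.2 left 9, 1, 8, 13, 36 and 11 genes. The shifts with the filters, the fold rules and the interval left out follow from their construction, since a looser rule admits more genes and a stricter one fewer. DESeq2 factors, total counts, TMM without mitochondrial and ribosomal protein genes and thinning to the smallest total kept each of the 6 counts within 1.5 times. The balance of higher and lower genes was not stable. Total counts changed TSA + phenamil against TSA from 30 higher and 20 lower to 20 and 23, TSA against young from 44 and 43 to 40 and 46, and TSA + phenamil against young from 16 and 12 to 13 and 13. TSA against senescent control changed from 7 and 13 to 34 and 26 without a filter, 67 and 64 at 1.5-fold, 66 and 62 with the deposited values and 8 and 9 after thinning. Senescent against young control changed from 14 and 19 to 89 and 76 at 1.5-fold and 73 and 62 with the deposited values. TSA + phenamil against senescent control changed from 10 and 10 to 48 and 29 without a filter, and TSA + phenamil against TSA from 30 and 20 to 3 and 10 with the assumed coefficient of variation. The share in the direction of young with TSA, 48.6%, was 75.8% without the split of control counts, 53.5% at 1.5-fold and 18.4% with at least 200 counts, so its majority direction depended on the setting. With TSA + phenamil it was 80.2%, 97.0% without the split, 77.95% at 1.5-fold, 99.3% with at least 200 counts and 95.1% at 4-fold. The shares with at least 200 counts rest on a mean of 4.35 genes and the one at 4-fold on 1.64. Their correlation of 0.231 was 0.443 without the split and 0.194 with at least 200 counts. The mean of 0.46 genes past the rule in both was 1 without the split, 0 with at least 200 counts, 0 at 4-fold and 3.81 at 1.5-fold. The cause was not tested for the direction and overlap shifts with at least 200 counts. Among 140 list medians, 12 moved past their counting interval with total counts and 2 with at least 200 counts, and among 1604 values of named genes 75 moved with total counts and 1 with the deposited log2 values. No paired analysis was possible because each group held 1 library, and leaving out a replicate or testing other splits of the samples was not possible for the same reason.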

Other observations

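The tests of the control library in a pair without it, of RNA from other cells, of depth in each form and of an exchanged TSA library were chosen after the result was seen, the tests of depth in list medians after tests on single members were inconclusive. The second pattern below was first stated as a young library not set apart from the others, and was restated after the counts of genes apart contradicted that. The readings of the bounds for exchanged labels and for the correlation of ratios as wrong also came after their values were seen.

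Of the variance between libraries over 1769 abundant genes, 51.2% lay in the contrast of the senescent control and TSA libraries against the young control and TSA + phenamil libraries, 35.2% in TSA-exposed against unexposed libraries and 13.5% in the remaining contrast. Collagens lay 0.68 (0.57 to 0.71) above glycolysis and hypoxia genes in TSA + phenamil against TSA, a pair without the senescent control. Error of that shared library cannot give this gap, which argues against it as the whole cause for these lists only. The gap restates list medians of 0.33 and -0.35 that were already seen in this pair. It is therefore no test of the pattern as a whole. The senescent/young and TSA/TSA + phenamil ratios, which share no library, correlated across 12228 genes at r = 0.192 (0.161 to 0.221 over resampled genes). The bound of 0.1 set before was wrong, because r is above 0 by algebra once the contrast with the greatest variance has been picked. The other such pairs gave -0.112 and 0.083. Over the 1769 abundant genes the values, in the same order, were 0.594, -0.445 and 0.2045. The signs of all these r values follow by algebra from which contrast varies more, so they are no test of the pattern. Removing the trend over gene span and expression left a gap between glycolysis and collagen medians of 0.53 (0.34 to 0.67) out of 0.56, and marrow cell markers reached at most 18.5 CPM, under the bound of 100. With 1 library in the largest group, a culture or library difference other than the named treatment cannot be told apart from the treatments, and an effect of phenamil on genes that differ with senescence is a candidate explanation that stays open and untested.

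Lists of senescence and mitosis genes had medians near 0 between the young and senescent control libraries, with members differing in both directions. Of cycle inhibitors and senescence genes 3 of 13 were higher and 2 lower in the senescent control, with Cdkn2b at 1.297 (1.198 to 1.404). The counts were 5 higher and 5 lower of 35 for mitosis and 7 and 9 of 27 for the secretory list. Genes lost in senescence had 1 of 9 lower and a median of 0.003 (-0.11 to 0.10). Depth is argued against for the list medians, whose counting intervals reached at most 0.14 from 0, but stays open for single members: 0 (0%) of 42 with 100 counts allowed a 2-fold difference, a filter that narrows intervals by itself, and without it 12.3% (7 of 57, 5.08% to 23.7%) did, across the bound of 20%. These members came from the lists of cycle inhibitors and senescence, of genes lost in senescence and of mitosis. The secretory list was not part of this test. An exchange of the young and TSA + phenamil labels was given a bound before the result was seen, that the young library have 1.5 times as many genes apart from the other 3, and the value of 1.95 (1.79 to 2.14, from 1434 and 734 genes) met it. That bound was wrong, because it supposes that no treated library stands apart as far as the young one, and the TSA library had 1472 such genes. The TSA-exposed pair as labelled held 35.2% of the variance in abundant genes against 13.5% for the young and TSA pair, which runs with the labels, but no bound was set for it, so the exchange stays open, and how the cells were made senescent may also matter but was not tested.

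The list of genes that respond to histone deacetylase inhibitors showed no set difference between the TSA library and the senescent control (median 0.07), although against the young control its median was 0.23 at percentile 98.7; it stood at 0.16 (percentile 99.1) in the senescent control and TSA pair over the other pair and at 0.07 (percentile 89.7) in TSA-exposed over unexposed libraries. A first depth test, on single members, found 14.3% (2 of 14, 1.78% to 42.8%) with an interval that allows a 2-fold higher level, both of them metallothionein genes, and this spread crosses the bound of 20%. Depth is argued against for the list as a whole, since the counting interval of its median reached only 0.12. An exchange of the TSA library with another of the 4 cannot be told apart from the labels: the highest list median of a library above the other 3 was 0.15, in the TSA library, with no spread between libraries of a group to set it against. Dose and the timing of a response at 24 h remain possible explanations that no value here tests.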
